A study of Sarcophaga bullata with 6 samples.

How the data were processed

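Small RNA was sequenced from whole pupae of the flesh fly Sarcophaga bullata. Per the labels' protocols, larvae whose mothers had not been through diapause were kept at 18 °C under long days, which avert diapause, or short days, which induce it. Pupae were taken at the phanerocephalic stage, when diapause begins. RNA was extracted pupa by pupa, and each library pooled 3 pupae of a group in equal parts; it was made with Illumina's TruSeq Small RNA kit and, per the series' design text, was run on a GAIIx instrument. There were 3 nondiapause libraries, numbered 1 to 3, and 3 diapause libraries, lettered A to C. The libraries of the groups shared no labels that would pair them.

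The authors trimmed the 3′ adapter and dropped reads under 15 nt, per the file headers. The remaining reads were mapped to arthropod entries of miRBase, a database of miRNAs, and to a set of contigs. The mapper, its version and the assembly build are not given in the sources used here. The deposited table gave raw expected counts per miRNA entry and library, because a read that mapped to several entries was split among them: 14.0% of the values were not whole. They were rounded to whole numbers before the count tests. A second set of columns held a normalized signal, which the authors made by dividing each raw value by a library size parameter of 0.85 to 1.40 and writing a raw 0 as 0.001, per the file headers. How these parameters were computed is not given in the sources used here. A list of hairpins gave pooled counts of each representative sequence over all libraries and its position on a contig, as deposited by the authors. A further file aligned the pooled reads to each hairpin, with base qualities.

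The table listed 846 named entries. Another 2 lines without a miRNA name held 0.00062% of the reads and stayed out of library sizes and tests. Entries were placed in 3 classes by name and length: mature miRNAs of 20 to 25 nt with the name of an annotated mature miRNA; other known-miRNA entries, which carried the name of a known miRNA hairpin or had another length; and predicted candidates, which the authors named PC. These classes were drawn up after the table was examined. In entry names, a suffix such as L-3 or R+1 gives bases lost or gained at an end. Several entries may name the same miRNA, and reads shared by near-identical copies were split between them.

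The main test was fixed before the data were examined: edgeR 4.0.16 quasi-likelihood tests with robust dispersions in R 4.3.3, on entries kept by filterByExpr with its minimum count of 10 and minimum total of 15, scaled with TMM (a trimmed mean of ratios between libraries). The contrast was diapause minus nondiapause, two-sided, with Benjamini-Hochberg adjustment over all tested entries and a threshold of 0.05. Every adjusted p given as edgeR's comes from this test, and CPM stands for TMM-scaled counts per 1000000 reads of the tested entries. TMM factors ran from 0.93 to 1.07 and the common dispersion was 0.0643. The design had assumed raw counts, and the same test was kept for the rounded expected counts.

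Also fixed then were 12 lists of miRNAs from work on Drosophila, matched by miRNA name in either arm: developmental timing and ecdysone, muscle, nervous system, insulin signalling and lipid metabolism, apoptosis, early embryo, circadian, testis, imaginal disc growth and patterning, innate immunity, gut and the K-box family. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The test used log2 CPM of counts summed by miRNA and arm, and was adjusted over the lists. A member counted as measured if it passed the count filter. The miRNAs named were set by a rule: up to 12 per direction with the largest change among those that passed, had a mean of at least 10 CPM and had ranges that did not overlap between groups; the 8 most abundant; and from each list up to 4 members that passed, or the member with the lowest p. In each part a miRNA name and arm with several entries was represented by its most abundant entry alone.

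On simulated data with the real means and library sizes, in which 200 of 748 entries were changed, 121 entries passed the filter. The test called 16 of 16 changed entries at a fold of 4 and 7 of 12 at a fold of 2 in the diapause against nondiapause contrast, with 0 wrong signs, and 2 of 93 unchanged entries. Rises and falls were planted in equal numbers without regard to class. The simulation therefore does not cover a shift by class like that in the real data, where the scaling matters. In a separate simulation only the entries of a planted list were lowered. That list was called, and 0 of 10 unchanged lists were. Entries were drawn independently, so this did not test the lists under correlation between miRNAs or a shift by class.

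Alternatives fixed in advance were scaling by RLE size factors, by library totals or by upper quartiles, no count filter or a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma on the authors' normalized signal with a pseudocount of 1 or 10, counts summed by miRNA and arm, predicted candidates or the 3 most abundant entries left out, and each library left out in turn. For the lists they were an estimated correlation and the self-contained test fry. Chosen after the data were seen were mappable reads as library size, the authors' parameters as library size, TMM factors from the mature miRNAs alone, tests of the mature miRNAs alone and a mature background for the lists. Shares were compared with exact two-sided permutation tests in scipy 1.17.1, which cannot give a p below 0.1 with 3 libraries against 3. Agreement of replicates was checked before averaging: chi-square per degree of freedom was 2.63 to 8.75 within groups, so no library was a copy of another. PCR copies were not separated, and the precision given by depth covers counting error only.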

Results

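Small RNA libraries of diapausing and nondiapausing flesh fly pupae were compared to find miRNAs whose abundance differs as pupae enter diapause, a programmed developmental arrest set by short days. Raw reads numbered 7927210 to 9682842 per library. Mappable reads were 7257278, 9027537 and 8561886 in nondiapause libraries 1, 2 and 3, and 7597345, 8289845 and 7079302 in diapause libraries A, B and C. The miRNA table held 28514, 35037 and 26837 reads of the nondiapause libraries and 30782, 32902 and 35542 of the diapause libraries, which was 0.313% to 0.502% of the mappable reads. What the other reads were is not given in the sources used here, so the values below describe the table and not all miRNA reads in the pupae. Pearson's r of log2 CPM across entries was 0.946 to 0.983 between libraries of the same group and 0.766 to 0.874 between groups; entries are not independent replicates. Among the diapause libraries C stood further from A and B (chi-square per degree of freedom 8.38 and 8.75) than A from B (2.63). Entries of 15 to 19 nt held 12.3% of its table reads, against 7.37% in A and 6.89% in B. Each library pooled 3 pupae, and p-values measure the spread between these pooled libraries.

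Mature miRNAs made up a smaller part of the table in diapause. They held 71.8% ± 2.18 (SD, n = 3) of its reads in nondiapause and 41.4% ± 3.79 (SD, n = 3) in diapause, and all 3 diapause libraries lay below all 3 nondiapause libraries (exact permutation p = 0.1, the smallest this design allows). Predicted candidates went from 21.3% ± 1.56 to 43.6% ± 1.36 and other known-miRNA entries from 6.89% ± 1.36 to 15% ± 3.20 (SD, n = 3; exact permutation p = 0.1 for each). Among single miRNAs, the steroid-timed let-7, miR-100 and miR-125, the growth regulators miR-8 and bantam, and miR-276a, the most abundant mature miRNA, were called lower in diapause, while entries named miR-2779 and miR-6497 and predicted candidates were called higher. With TMM factors from mature miRNAs alone the call was lost by let-7-5p, by both arms of miR-8 and of bantam and by miR-276a-3p. bantam-3p lost it in 9 of 16 settings other than leaving out a library. Per 1000000 mappable reads, mature miRNAs numbered 2740, 2880 and 2250 in nondiapause libraries 1, 2 and 3, and 1740, 1760 and 1860 in diapause libraries A, B and C, while the other entries numbered 1190, 1000 and 889, and 2320, 2210 and 3160.

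**Figure D1:**
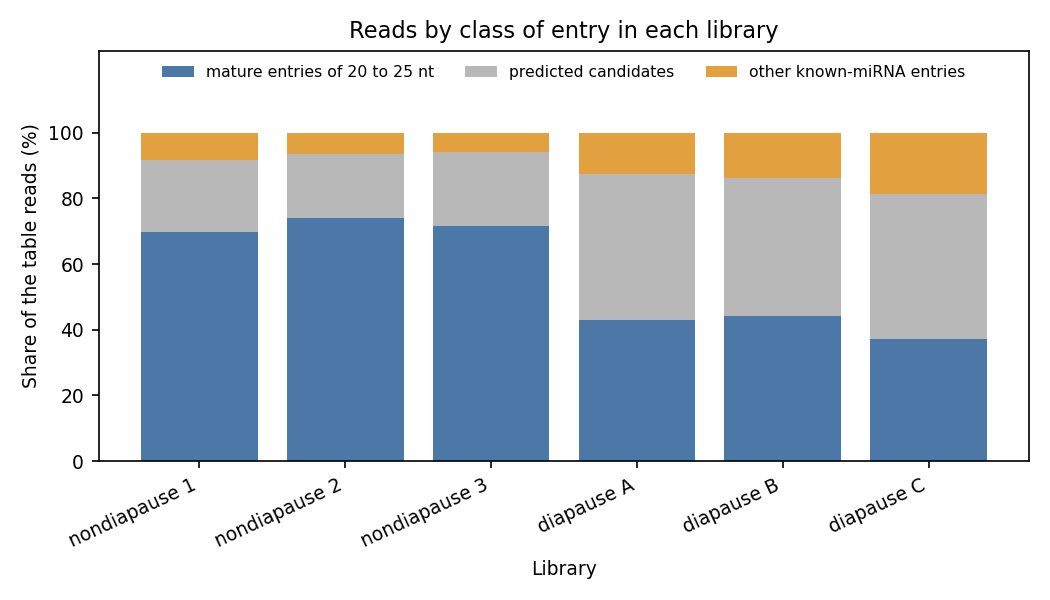
Share of the table reads (%, vertical axis) in each of the 6 libraries, stacked by class of entry. Mature miRNAs of 20 to 25 nt held 69.8% to 74.1% in the nondiapause libraries and 37.1% to 44.3% in the diapause libraries.

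Of 846 entries, 121 had enough reads to test, and 66 were called at an adjusted p under the threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 31 higher and 35 lower in diapause. Among 61 mature miRNAs, 33 were lower and 0 higher, with a median log2 fold change of -0.72. At an unadjusted p under 0.05 in edgeR, 1 mature miRNA was higher, miR-190-5p, named because it was the only such entry, and DESeq2 and limma-voom called 0 higher. Among settings fixed in advance, 1 mature miRNA was called higher with RLE size factors and 1 with upper-quartile factors, 2 with limma on the authors' signal, 2 without candidates and 3 with at least 50 counts required. Leaving out a library gave 1 without nondiapause replicate 1, 2 or 3, 2 without diapause replicate C and 0 without A or B. Other known-miRNA entries gave 17 higher and 1 lower of 33 with a median of 1.20, and predicted candidates 14 higher and 1 lower of 27 with a median of 0.89. The 17 carried 6 miRNA names. Most were overlapping miR-6497 or miR-2779 sequences that shared reads, so they do not stand for 17 separate RNAs. The median over all tested entries was -0.18, and scaling moved it. Higher calls were 47.0% of all calls with TMM, but 66.7% with upper-quartile factors (38 higher, 19 lower), 68.5% with the authors' library size parameters (37 higher, 17 lower) and 81.5% with TMM factors from mature miRNAs alone (44 higher, 10 lower), which shifted the median by 0.20, 0.39 and 0.66. With the last of these, 7 mature miRNAs were called higher and 8 lower. Over 7 ways of scaling, 29 entries were called higher in each, none of them mature, and 10 were called lower in each, 8 of them mature.

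**Figure D2:**
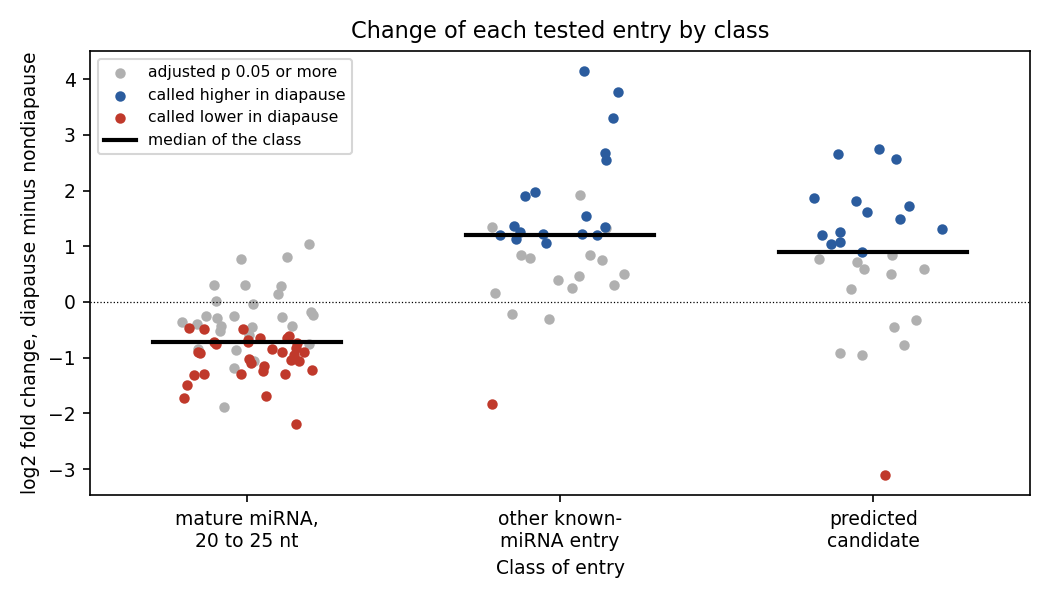
The log2 fold change of each of the 121 tested entries (vertical axis, diapause minus nondiapause) by class of entry; each point is an entry, coloured by its call in edgeR, and the bar is the class median. The medians were -0.72 for mature miRNAs, 1.20 for other known-miRNA entries and 0.89 for predicted candidates; with TMM factors from mature miRNAs alone the mature median was -0.06.

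Those 8 mature entries, lower with each scaling, included the let-7 complex partners miR-100-5p and miR-125-5p. In Drosophila, let-7, miR-100 and miR-125 come from a shared transcript that is switched on around metamorphosis, and here their hairpins lay together on Contig15 of the authors' assembly (positions 345101 to 345171, 345441 to 345528 and 344483 to 344574; build not given in the sources used here, and no gene annotation was used). miR-125-5p (TCCCTGAGACCCTAACTTGTGA) fell from 4200 ± 1630 to 1260 ± 178 CPM (SD, n = 3), a log2 fold change of -1.73 ± 0.30 (SE; edgeR adjusted p = 0.00169), but did not pass when mature miRNAs were tested alone (-1.09, edgeR adjusted p = 0.0877). miR-100-5p fell by 1.29 ± 0.23 on the log2 scale (edgeR adjusted p = 0.0017). A second, less abundant miR-100-5p entry was not called (-1.88 ± 1.03 SE, edgeR adjusted p = 0.144). It had 106 reads in nondiapause library 1 and 4 to 15 in each other library. let-7-5p, the partner of miR-100 and miR-125, fell by 1.24 ± 0.21 (edgeR adjusted p = 0.00149), from 7400 ± 1370 to 3140 ± 406 CPM (SD, n = 3). It stood at -0.57 with TMM factors from mature miRNAs alone (edgeR adjusted p = 0.101). The 8 also held miR-31a-5p in 2 forms. miR-31a-5p, known from embryonic segmentation (Contig220, 391160 to 391253), fell by 1.22 ± 0.16 from 25700 ± 166 to 11000 ± 1800 CPM (SD, n = 3; edgeR adjusted p = 0.000778). miR-305-5p and miR-275-5p, whose hairpins are neighbours on Contig56 (826110 to 826181 and 825818 to 825918), fell, with log2 fold changes of -1.02 ± 0.15 and -2.20 ± 0.47 SE (edgeR adjusted p = 0.00121 and 0.00397); miR-275-5p rested on 2 to 22 reads per library. miR-958-3p and miR-13b-3p fell, with log2 fold changes of -1.29 ± 0.22 and -1.50 ± 0.31 SE (edgeR adjusted p = 0.00149 and 0.00333), and miR-13b shares sequence with other members of the miR-2 family, so its reads are uncertain.

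**Figure D3:**
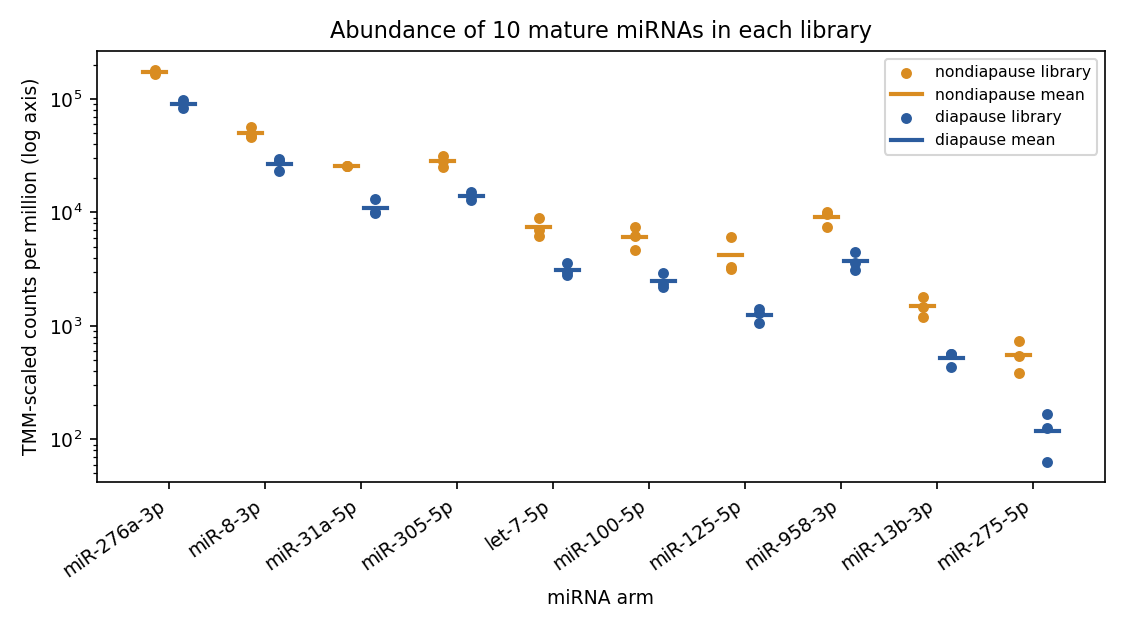
TMM-scaled counts per 1000000 reads (CPM, log axis) of 10 mature miRNA arms in each library; points are libraries and bars are group means. In all 10 the 3 diapause libraries lay below the 3 nondiapause libraries; with TMM factors from mature miRNAs alone miR-276a-3p, miR-8-3p and let-7-5p no longer passed the test, at log2 fold changes of -0.25, -0.22 and -0.57.

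In the main test the most abundant mature miRNAs moved less than those 8 entries, which were set apart by keeping their call with each scaling. The size of the 8 falls still leaned on the scaling. At the scaling that gave each its smallest fall, they stood between -0.35 (miR-305-5p) and -1.56 (miR-275-5p). Among them miR-31a-5p stood at -0.56, miR-958-3p at -0.61 and miR-100-5p at -0.62. The calls of the most abundant mature miRNAs leaned on the scaling, as did those of most of the 33 mature miRNAs called lower. miR-276a-3p, linked to memory and circadian behaviour in Drosophila (Contig111, 266135 to 266214), went from 173000 ± 6420 to 91000 ± 7690 CPM (SD, n = 3; log2 fold change -0.92 ± 0.11 SE, edgeR adjusted p = 0.000678), and its near-identical copy miR-276b-3p makes the split of reads between them uncertain. miR-8-3p, a regulator of insulin signalling and body growth, fell by 0.89 ± 0.15 (edgeR adjusted p = 0.00149). bantam-3p, which promotes growth and blocks apoptosis, fell by 0.64 ± 0.16 (edgeR adjusted p = 0.0086), and miR-275-3p by 0.46 ± 0.14 (edgeR adjusted p = 0.0198). With TMM factors from mature miRNAs alone, miR-276a-3p stood at -0.25 and miR-8-3p at -0.22, neither past the test, and bantam-3p stood at 0.03 and miR-275-3p at 0.21. miR-275-3p lost its call in 13 of 16 settings other than leaving out a library. miR-282-5p differed by -0.27 ± 0.14 (edgeR adjusted p = 0.117), and its calls went both ways: lower with library totals (-0.35, edgeR adjusted p = 0.0356) and higher with TMM factors from mature miRNAs alone (0.40, edgeR adjusted p = 0.0094).

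Groups fixed in advance were mostly lower. Among 12 arms of the insulin signalling and lipid metabolism list, 10 fell and 11 did so when adjusted over the list alone, among them miR-8, bantam, miR-275 and both arms of miR-305. Of 8 arms in the developmental timing and ecdysone list 7 fell, and 8 adjusted over the list alone; miR-281-5p, a regulator of the ecdysone receptor in the silkworm, was at -1.30 ± 0.40 SE, a call lost in 10 of 15 settings other than leaving out a library, DESeq2 among them (adjusted p = 0.259). The imaginal disc list had 10 of 14 arms lower (12 adjusted over the list alone), with miR-9a-5p at -0.69 (call lost in 9 of 16 such settings), and the innate immunity list 6 of 7 (6), with miR-958-3p. All 6 arms of the gut list tested as entries fell (6), and 6 of 9 of the apoptosis list (6). Among the latter were bantam-5p (-1.69) and miR-11-3p (-1.15), which stood at -0.47 with TMM factors from mature miRNAs alone (edgeR adjusted p = 0.0502). On counts summed by miRNA and arm, camera tested 9 arms of the developmental timing list and 7 of the gut list. These 6 lists were called lower by camera, with adjusted p = 0.00358, 0.00358, 0.00358, 0.00846, 0.0187 and 0.0249, but each gave adjusted p = 0.33 with an estimated correlation. They share members, and against a background of mature miRNAs alone no list was called (lowest adjusted p = 0.122; 3 of 10 lists had an unadjusted p under 0.05).

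The remaining lists were not called in the main test. In the circadian list 5 of 8 arms fell (5 adjusted over the list alone, camera adjusted p = 0.0522), led by miR-276a-3p and let-7-5p. The list was called lower with library totals and with entries as listed (camera adjusted p = 0.0341 and 0.0285). With an estimated correlation it gave camera adjusted p = 0.33, and against the mature background it turned upward (camera adjusted p = 0.818). The nervous system list had 5 of 15 arms lower (5), including miR-9c-5p at -0.95 and miR-9a-3p at -0.85, whose calls were lost in 3 and 10 of 16 settings other than leaving out a library, and the K-box family 2 of 3 (2), miR-11-3p and miR-13b-3p (camera adjusted p = 0.376 and 0.10). In the muscle list 1 of 4 arms fell (1), miR-92b-3p at -1.05 ± 0.30 SE (camera adjusted p = 0.537 for the list). Its call was lost in 10 of 15 such settings, DESeq2 among them (adjusted p = 0.0786), and its reads are uncertain because miR-92a is a near copy. miR-1, the muscle miRNA, named after its value was seen, stood at -0.03 ± 0.18 SE (edgeR adjusted p = 0.894). In the hairpin alignments 1.56% of its copies had no mismatch, against a median of 80.9% in the other mature miRNAs. None of the early embryo members had an entry with enough reads to test. The testis list had 1 such entry, of 15 nt, named miR-977-3p: its log2 fold change was 1.34 ± 0.54 SE (edgeR adjusted p = 0.0646). It passed when adjusted over the list alone, in 7 of 14 other settings and without nondiapause replicate 1.

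Entries that rose were mostly short, long or predicted sequences. The candidate PC-5p-5395_463 (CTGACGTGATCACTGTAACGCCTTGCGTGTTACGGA, Contig153611, 5 to 96) rose from 8200 ± 610 to 54800 ± 8040 CPM (SD, n = 3), a log2 fold change of 2.74 ± 0.16 SE (edgeR adjusted p = 5.46e-06). PC-3p-4142_589 and PC-5p-1003_2057, among the most abundant entries of the table, rose by 1.04 ± 0.14 and 1.08 ± 0.16 (edgeR adjusted p = 0.000778 and 0.000957). A miR-2779 entry of 16 nt, TCCGGCTCGAAGGACC (Contig11807, 1150 to 1181), rose by 3.78 ± 0.49, and its variant TCCGGCTCGAAGTACC by 3.31 ± 0.51 (edgeR adjusted p = 0.000836 and 0.00149). Diapause library C held the most reads of both. Without it they rose by 3.27 and 2.74. A less abundant miR-2779 entry of 17 nt, named after its value was seen, had the largest rise of all, 4.15 ± 0.48 SE (edgeR adjusted p = 0.000678), on 3.2, 2.6 and 0.8 expected reads in the nondiapause libraries. The most abundant miR-6497 entry (TCGGGATAAGGATTGGCTCT, Contig224993, 1 to 80) rose by 1.23 ± 0.21 (edgeR adjusted p = 0.00149). Together miR-2779 and miR-6497 entries held 4.59% ± 0.59 of the table in nondiapause and 11.6% ± 2.12 in diapause (SD, n = 3; exact permutation p = 0.1). In the 17 known-miRNA entries that rose, a median of 56.1% of aligned copies began at the most frequent 5′ end, against 99.3% in the 61 mature miRNAs. Entries of the same name shared most of these copies. Over the 6 names the median was 66.5%, with a range of 17.3% to 97.8%, the highest at miR-2494. Copies without a mismatch made up 80.3% at miR-2779, but 4.28% at miR-3772, 0.82% at miR-307 and 0.0% at miR-2494 and miR-289. The most abundant miR-6497 entry stood at 0.979%. The median was 80.9% in mature miRNAs other than miR-1. Some entries of this class that were not called also stood at 0.0%, such as miR-977-3p. The other named rises were PC-3p-43567_47 (2.66), PC-5p-75438_22 (2.57), miR-289 (1.97), miR-2494 (1.91), PC-5p-23453_100 (1.86), PC-5p-51204_38 (1.82), PC-3p-7368_341 (1.73), PC-5p-89283_17 (1.61) and miR-3772 (1.55).

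Among entries outside the mature class 2 were lower. PC-5p-56607_33 (CAGTCCGTCATTTGGCAACCTAGC, Contig404, 53352 to 53414), which lies beside miR-980-3p on the same strand, went from 397 ± 97.2 to 42.4 ± 17.4 CPM (SD, n = 3), a log2 fold change of -3.11 ± 0.48 SE (edgeR adjusted p = 0.00126), on 9 to 18 reads per nondiapause library and 1 to 2 per diapause library. A miR-305-3p entry (CGGCACATGCTGAAGTACATTCA, Contig56, 826103 to 826188) fell by 1.83 ± 0.34 (edgeR adjusted p = 0.00202). Of the named calls, those of PC-5p-75438_22, PC-5p-51204_38, bantam-3p and miR-9a-5p did not pass without a certain library. Those of PC-5p-89283_17, miR-3772, miR-281-5p, miR-275-3p, miR-92b-3p and miR-9a-3p did not pass without either of 2 libraries, with the direction kept in each. Leaving out a library also moved the size of some rises: the log2 fold change of PC-5p-75438_22, on 0 to 11 reads per nondiapause library, ran from 2.26 to 3.56, that of PC-5p-89283_17 from 1.38 to 2.25, that of PC-5p-51204_38 from 1.30 to 2.30 and that of miR-3772 from 1.30 to 2.13.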

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

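The tests in this part were chosen after the results were seen. The hairpin list held 5 sequences with more pooled copies than a count of 0 allows (3) and no values per library, so no comparison between diapause and nondiapause could use them. Their pooled copies over all libraries were 42 for GTTCATATCCGGCTCGAA, 39 for TTCGGGATAAGGATT, 38 for TCCGGGTTCGTTTCC, 14 for TGGTTCATATCCGGCTCGAA and 8 for GTTCATATCCGGCTCGA. No explanation was tested for them. Groups of 3 libraries are too small for the outlier test, so no single library was tested for standing apart. By description, diapause library C differed from A and B by a chi-square per degree of freedom of 8.38 and 8.75, against 2.63 between A and B and 5.09 to 7.58 in the nondiapause group.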

How the results depend on the processing

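The settings chosen after the data were seen were mappable reads and the authors' parameters as library sizes, TMM factors or tests from mature miRNAs alone, the mature background and shares of mappable reads. No paired analysis was possible, as the groups share no replicate label. No entry called in the main test was called in the other direction in the settings that kept the entries as listed. Of 39 named miRNAs, 19 kept sign and call in every setting run, 16 lost the call in some setting, 3 changed sign and 1 gained a call. Against 66 calls there were 34 with 50 counts required, 36 without candidates and 23 among mature miRNAs alone, which test fewer entries and kept 31, 32 and 12; higher calls were 48 without a filter, 20 with 50 counts and 11 among mature miRNAs, against 31. Lower calls, 35 in the main test, were 19 with upper-quartile factors, 14 with 50 counts, 17 and 17 with limma on the authors' signal plus 1 or 10, 18 with summed counts, 15 without candidates, 10 with mature TMM factors, 17 with the authors' parameters and 12 among mature miRNAs. Leaving out a library gave 60 to 75 calls, 30 to 43 higher and 23 to 36 lower; the 23 came without nondiapause replicate 3. Called lists fell from 6 to 0 with an estimated correlation and to 0 with the mature background, where muscle, nervous system and circadian turned upward (unadjusted p = 0.236, 0.0279 and 0.818); leaving out a library gave 5 to 7. miR-282-5p turned to 0.16 with 50 counts, 0.12 with the authors' signal plus 1 or 10 and with the authors' parameters, 0.19 without candidates and 0.40 with mature TMM factors or mature miRNAs alone, past the test in both of these. miR-275-3p went to 0.00 without candidates and 0.21 with the last settings, and bantam-3p to 0.03. The difference in mature share, -30.39 points, was -4.50 over distinct sequences and -0.08 points of mappable reads, and that of candidates was -1.58 over distinct sequences; without the 3 most abundant sequences candidates rose by 14.01 points, against 22.32, and other known-miRNA entries by 13.71, against 8.07; leaving out a library gave a mature difference of -31.83 to -28.24. Calls were lost (edgeR adjusted p, Benjamini-Hochberg) without nondiapause replicate 1 for miR-275-3p (0.127) and miR-92b-3p (0.0666), without replicate 2 for miR-3772 (0.0682), and without replicate 3 for miR-275-3p (0.189), bantam-3p (0.0744), miR-92b-3p (0.059), miR-9a-5p (0.0541) and miR-9a-3p (0.0536); without diapause replicate A for PC-5p-89283_17 (0.0796), miR-281-5p (0.0526) and miR-9a-3p (0.0508), without B for PC-5p-75438_22 (0.057), PC-5p-51204_38 (0.0515), PC-5p-89283_17 (0.0918) and miR-281-5p (0.0703), and without C for miR-3772 (0.0565). Calls were gained for miR-282-5p without diapause replicate B (0.0413) and miR-977-3p without nondiapause replicate 1 (0.00521). The circadian list was called without diapause replicate B (camera adjusted p = 0.0498), with library totals (0.0341) and with entries as listed (0.0285); the innate immunity list was lost without C (0.0749) and the apoptosis list without a filter (0.444). fry, without a background, called 8 lists by direction, adding circadian (0.0102) and K-box (0.0153), and 9 mixed, adding nervous system (0.00508). Causes of changes were not tested. Depth limits the low entries: 121 of 846 could be tested.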

Other observations

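All tests in this part were chosen after the results were seen, and the bounds of those on base quality, the T-loop motif and neighbouring miRNAs were tightened after a first result, which left each undecided. The arms of single hairpins changed by different amounts, a comparison that scaling between libraries does not touch. In 9 hairpins with a mature miRNA and at least 30 reads of 20 to 26 nt in each arm, the log2 ratio of the less to the more abundant arm (pseudocount 0.5) was compared. At miR-8 on Contig1195 the 3p arm counted as the less abundant, with 42 reads against 551, because most miR-8-3p reads were listed on Contig8998. Its difference was 0.22 there, and -0.2 with reads from both contigs. Arms were paired when their listed hairpins overlapped by at least 80%; a first, wider pairing had joined neighbouring hairpins at miR-980 and miR-278, which were dropped. The ratio fell from -6.23 ± 0.55 to -7.90 ± 0.57 (SD, n = 3) at miR-275 (Contig56, 825818 to 825918), a difference of -1.67, and differed by -1.09 at bantam and -0.80 at miR-305. At miR-276a it went the other way, from -7.23 ± 0.16 to -6.01 ± 0.05, a difference of 1.22. Each of these 4 had an exact permutation p of 0.1, the smallest possible.

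Chance overlap alone would separate the groups in 10% of hairpins, and 4 of 9 were separated (exact binomial p = 0.00833), which argues against counting noise of the minor arm for the set. Reads shared with miR-276b-3p do not account for miR-276a, where the difference was 1.20 with those reads added. A hypothesis is that minor arms may fall more than major arms in diapause: 7 of 9 differences lay below 0 (exact sign test, two-sided p = 0.18), and 8 of 9 when miR-8 reads from both contigs were paired (p = 0.0391). In 6 hairpins without a mature miRNA, with reads of any length, 4 lay below 0. With miR-8 from Contig1195 alone this made 11 of 15 in all (exact sign test, two-sided p = 0.118). The total with miR-8 from both contigs was not tested. Of the 6, PC-3p-4142_589 and PC-3p-5977_418 lay on opposite strands of the same stretch of Contig94559, so their signs are not independent. The hypothesis stays open. Among the 6, the largest difference against it was 0.72, at PC-3p-43567_47. Arm choice or arm stability was not tested.

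A second pattern is that mature miRNAs fell while other entries rose. Reads taken by the risen entries within the table cannot be the whole of it, since per 1000000 mappable reads the diapause libraries held 68.1% of the nondiapause mean of mature miRNAs, with no overlap. More reads of RNAs with no fragments in the table would lower all its entries alike and do not account for the rise. Per 1000000 mappable reads the other entries ran from 889 to 1190 in nondiapause and from 2210 to 3160 in diapause, 249% of the nondiapause mean. These values cannot exclude RNAs outside the table whose fragments are counted among the risen entries. The table's share of mappable reads rose too, from 0.365% to 0.435% (exact permutation p = 0.1). For the fall of the mature miRNAs, a shift in RNAs outside the table cannot be told apart from a lower miRNA content, because those reads, 99.6% of the mappable, are not counted by kind of RNA. Degraded RNA cannot be told apart either, as reads under 15 nt differed by 0.28 points (exact permutation p = 0.9). The risen known-miRNA entries may be fragments of longer RNAs. A median of 56.1% of their copies began at the most frequent 5′ end, or 66.5% over their 6 miRNA names. The lower quartile was 98.3% in mature miRNAs, and the median was 95.1% in the 16 other known-miRNA entries that did not rise. The contrast had exceptions on both sides: a risen miR-2494 entry stood at 97.8% and an unrisen miR-6497 entry at 11.5%. The miR-2494 entry had no listed contig position, and 0.0% of its copies aligned without a mismatch. The risen candidates had no alignments to test, and diapause itself stays among the open explanations.

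miR-1 was counted from reads that carry a mismatch. Its entry TTGAATGTAAAGAAGTATGGAG differs from TGGAATGTAAAGAAGTATGGAG on Contig943 (23663 to 23741) by G2T, counted from 1 at the 5′ end with the base of the contig first, and 0 of 2765 pooled copies had the exact sequence; 43 shorter copies without a mismatch began at position 3 or later. A variant shared by all the flies does not explain this, because 17.7% of copies had the contig's base at position 2, with mismatches at 13 positions in all. Sequencing errors in exact reads that were counted elsewhere could: base quality was 10 lower at the mismatch than in the rest of the read, but 5 lower at position 2 in exact reads of other miRNAs too, so this stays open.

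Among candidates called higher, 2 of 14 lay in loci with the T-loop motif of tRNA genes, against 0 of 13 other candidates and 0 of 61 mature miRNAs (Fisher's exact p = 0.481 for the candidates). Only these 2 candidate loci held the motif, so this test could not have given a p under 0.05. It left undecided whether rises go with tRNA loci, and it did not test the origin of these 2 candidates. The 2 candidates are PC-5p-32811_67 (Contig2486, 11595 to 11670, log2 fold change 1.49 ± 0.28 SE) and PC-5p-75438_22 (Contig62493, 583 to 685, 2.57 ± 0.69 SE). They differ from their contigs by A1G and G9T, counted from 1 at the read's 5′ end with the base of the contig first.

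miRNAs encoded within 50 kb of each other on the same strand did not change more alike than random pairs. In 9 pairs of neighbouring miRNAs the mean absolute difference of log2 fold changes was 0.65, against 0.61 in random pairs (permutation p = 0.601, 10000 permutations). let-7-5p and miR-100-5p differed by 0.05, while miR-279-3p and miR-996-3p, at -0.44 and 0.80, differed by 1.24.

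Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many called entries, the real split with 66, and the highest other gave 0. For called lists, 2 splits gave as many, the real split with 6 and another with 6. With 10 splits the share cannot go below 0.1, which is too few for a share under 0.05.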
